A study of Mus musculus with 2 samples.

How the data were processed

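Nuclei-containing live tdTomato-positive cells were sorted from enzymatically digested graft tissue after the adventitia had been removed, and were profiled with a droplet-based 3' single-cell kit with UMIs, per the labels' protocols. Reads were processed with Cell Ranger 3.0.2 against mm10, per the submitters' processing notes. For each sample the authors deposited a sparse matrix of UMI counts per gene and barcode, with lists of genes and barcodes. The values were whole numbers, and the lowest barcode total was 500 UMIs in both libraries. The matrices held 31054 features, 1 of which was a custom row for tdTomato. How barcodes were selected before deposit is not given in the sources used here.

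Samples were grouped by the time after surgery in the labels, with 1 library at 2 weeks and 1 library at 4 weeks. Markers, gene lists, filters, comparisons and the other settings below were chosen before the data were examined. Cells with at least 300 detected genes and at most 10% mitochondrial UMIs were kept: 46 and 77 barcodes fell below the gene minimum, and 471 and 585 exceeded the mitochondrial limit. Scrublet, as implemented in scanpy 1.11.5, called 0 doublets in each library against expected rates of 3.84% and 4.22%. The caller thus did not work, and no cell was removed as a doublet in the main analysis. Counts were scaled to 10000 per cell and log-transformed. With 2000 variable genes chosen across both libraries, 30 principal components and 15 neighbours, Leiden clustering at resolution 1.0 (leidenalg 0.10.2) gave 27 clusters.

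A cluster took the name of the marker list with the highest score, as "X-like". Rules set after the data were seen kept a cluster unnamed if cycling genes scored highest, or if markers of more than 1 lineage reached 0.2 of their highest cluster level. It also stayed unnamed with under 3 markers detected in 10% of its cells, with more markers of another class than of its own among its 10 leading genes, or with a low UMI count and no own marker among them. Low meant a median below that of its sample divided by 3. Differences from published cell types may come from these names. Classes with at least 50 cells in each library were compared: macrophage or monocyte, neutrophil, dendritic cell and T cell. The smooth muscle and fibroblast list comparisons were planned but had too few cells.

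Shares carry exact Clopper-Pearson intervals and differences of shares carry Newcombe intervals. UMIs were summed per class and library and scaled to CPM, which puts every sum on the same total. The ratio of a gene is the log2 of its CPM at 4 weeks over that at 2 weeks, with 0.5 counts added to each sum and an exact conditional interval of Poisson counts. A list is summarised by the median ratio of members with at least 20 counts, with an interval from 1000 Poisson resamplings, and by the percentile of that median among 10000 random lists matched in 20 bins of mean expression. For shares of cells with a UMI, each cell was thinned at random to 2000 UMIs and shallower cells were left out. All intervals are at the 95% level, treat UMIs or cells as independent, and cover counting error only. They are widest for genes of few counts and classes of few cells.

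The genes named in a class are the 10 highest and 10 lowest log2 ratios among genes with at least 100 counts, at least 50 CPM in the higher library and a UMI in at least 5% of its cells there. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes and the genes of a fixed sex and strain list were not eligible. They are given for the 3 largest classes, except 1 gene that is not reported here. For each main pair of class and list, the members with the highest CPM and the largest ratio are named, as is Kit. Other genes are named as examples chosen after their values were seen. Among them are Chil3, Gzmb, Ifng and Prf1 as list members, markers of the vessel wall, and leading or marker genes of clusters. Gene positions come from GENCODE M21 on GRCm38, the assembly also called mm10, matched by Ensembl identifier. For the named genes, 50-base windows of the last 300 transcript bases were searched in the transcripts of all other genes.

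The ratio and list steps were tested on counts simulated from the sums of the macrophage-like class. Each gene was drawn as an independent Poisson count, which is what the intervals assume. The simulation therefore cannot show how they behave when UMIs lie in few cells or genes vary together. In that simulation of 9789 genes, the intervals of all genes changed 2-fold or 4-fold excluded 0, as did those of 5.9% of the unchanged genes. A list of 15 genes changed 2-fold lay at percentile 100. A list of 15 unchanged genes lay at percentile 98.1, and of 200 such lists 5.5% lay outside the central 95% of random lists.

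Other settings chosen beforehand were a minimum of 800 genes, a mitochondrial limit of 20%, resolutions 0.5 and 2.0, 4000 variable genes, clustering of each library alone, clustering without proliferation and stress genes, thinning to 1000 UMIs or none, TMM scaling (edgeR 4.0.16, R 4.3.3), doublets kept, list members with at least 100 counts, 5 counts added, and the mean over cells. Settings added after the data were seen were removal of the highest doublet scores up to the expected rate, use of cells with Xist and without Y-linked UMIs, and return of clusters that failed a naming rule. Clusters led by cycling genes, with markers of more than 1 lineage or with under 3 detected markers were not returned. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.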

Results

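Single-cell transcriptomes were collected from mouse aortic grafts to ask which cells derived from the recipient's c-Kit lineage occupy an allogeneic vessel graft, and how they differ between 2 and 4 weeks after transplantation. Aortas of BALB/c donors were grafted into recipients on another background that carried a tamoxifen-inducible Cre under the Kit promoter and a Cre-dependent tdTomato reporter. Kit encodes the receptor of stem cell factor and marks haematopoietic progenitors and mast cells. The adventitia was dissected away, and live nucleated tdTomato-positive cells of the medial and neointimal layers were sorted, so every share below is a share of sorted cells. There was 1 library per time point, with 5271 barcodes and 33008959 unique molecular identifiers (UMIs) at 2 weeks, and 5883 barcodes and 32388344 UMIs at 4 weeks. After filtering, 4794 and 5277 cells were kept, with median depths of 6331 and 5201 UMIs. With no replicates there was no test between time points. Intervals are 95% intervals of counting error alone, and differences between animals, sorts or library batches cannot be separated from time.

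Leukocytes made up nearly the whole of both libraries. Macrophage- or monocyte-like cells, called macrophage-like from here on, were the most frequent class, at 51.6% of kept cells at 2 weeks (exact binomial interval 50.2 to 53.0, 2474 cells) and 57.6% at 4 weeks (56.2 to 58.9, 3037 cells). Neutrophil-like cells were less frequent at 4 weeks, at 9.76% (8.97 to 10.6) against 20.1% (19.0 to 21.3), a difference of -10.4 percentage points (Newcombe interval -11.8 to -8.98). T cell-like cells were more frequent at 4 weeks, at 7.81% (7.10 to 8.56) against 3.88% (3.35 to 4.47). That count leaves out cluster 17, which carried T cell and macrophage markers in the same cells. This cluster held 187 cells (3.90%) at 2 weeks and 40 (0.758%) at 4 weeks. Its share differed by -3.14 points, against 3.93 points for T cell-like cells. Counting the cluster as T cells would thus remove most of the T cell-like difference. NK cell-like cells were also more frequent at 4 weeks, with 149 of 5277 cells (2.82%, interval 2.39 to 3.31) against 25 of 4794 (0.521%, interval 0.338 to 0.769). Dendritic cell-like cells accounted for 6.05% (5.39 to 6.76) and 7.98% (7.26 to 8.74).

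Smaller classes each held under 1% of the cells. There were 13 and 38 endothelial-like cells at 2 and 4 weeks, 11 and 36 plasmacytoid dendritic cell-like cells, 23 and 15 B or plasma cell-like cells, and 8 and 12 mast cell- or basophil-like cells. Clusters that failed a naming rule were kept out of the classes. These were cluster 4, led by Mmp19, Spp1, Pdpn and Arg1 (6.30% and 6.69% of cells), and cluster 14, of low UMI count and led by Clic5, Il1a and Cd274 (5.26% and 0.815%). Macrophage markers were found in cluster 4: Cd68 in 89.4% and 79.3% of its cells, Csf1r in 89.1% and 76.2%, and C1qa in 45.0% and 38.2%. The others were cluster 17, with T cell and macrophage markers in the same cells (3.90% and 0.758%), cluster 20, led by Retnla and Ear2 (0.375% and 1.93%), and cluster 21, led by cell cycle genes (0.542% and 1.67%).

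The neutrophil-like difference kept its direction but ranged from -14.8 to -6.16 points over the other clustering and filter settings, and these cells were the shallowest, with median depths of 1687 and 1319 UMIs. The macrophage-like difference of 5.95 points fell to 2.27 with a minimum of 800 genes per cell, and to 1.42 (-0.566 to 3.41) when the failing clusters were also put back. It was 8.73 with a mitochondrial limit of 20% and 8.99 in cells with Xist and no Y-linked UMI. It turned to -2.48 when the cells with the highest doublet scores were removed, because a cluster of 919 cells then failed a naming rule, and was 5.82 with the failing clusters put back. In cells with Xist and no Y-linked UMI, the dendritic cell-like difference was 3.22 points instead of 1.93.

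**Figure D1:**
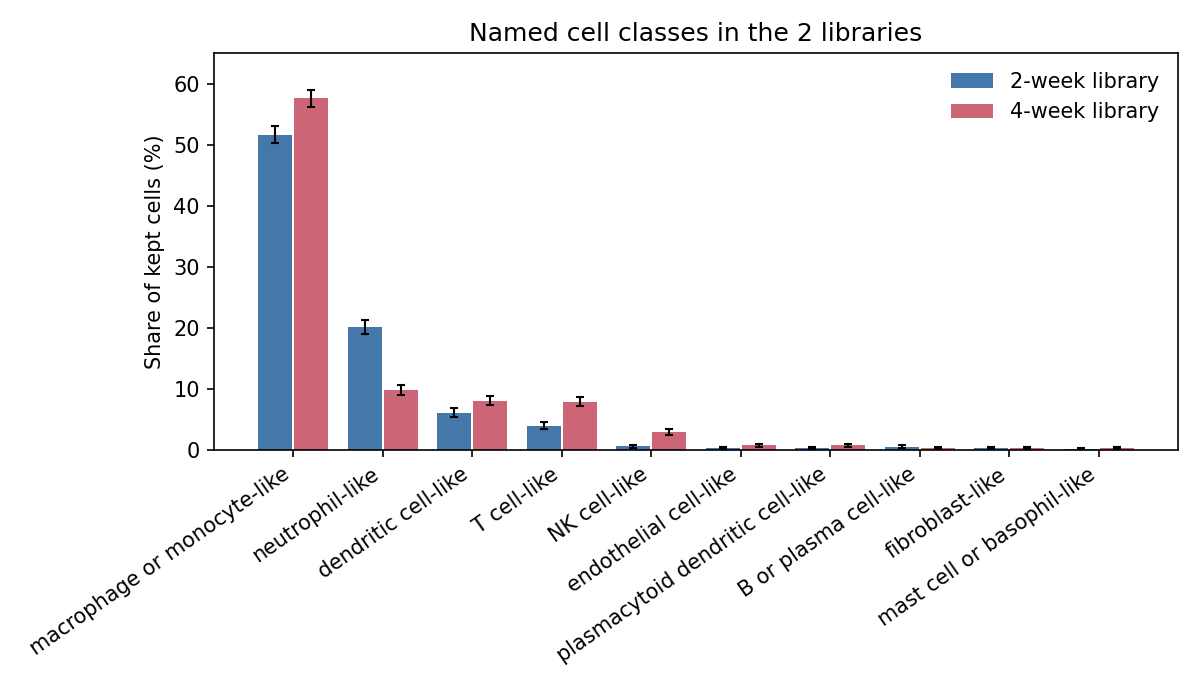
Share of kept cells (%) in each named class, with the 2-week library in blue and the 4-week library in red. Bars are shares and error bars are exact 95% binomial intervals. The neutrophil-like share was 20.1% at 2 weeks and 9.76% at 4 weeks, and the T cell-like share was 3.88% and 7.81%. The T cell-like bars leave out cluster 17, with T cell and macrophage markers in the same cells, which would remove most of that difference.

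Few sorted cells were named as cells of the vessel wall. No cluster was named smooth muscle cell or pericyte. Myh11, the smooth muscle myosin heavy chain (ENSMUSG00000018830, GRCm38 chromosome 16, 14194535 to 14291372), had 13 UMIs in 5 of 4794 cells at 2 weeks and was found in 0 of 5277 cells at 4 weeks, where the exact upper bound of 0.070% limits cells with a UMI, not cells that express the gene. Cnn1, which encodes calponin, had 4 UMIs at 2 weeks and 1 at 4 weeks. The fibroblast-like class held 14 cells at 2 weeks and 16 at 4 weeks, or 0.292% (0.160 to 0.489) and 0.303% (0.173 to 0.492). Too few for the planned list comparisons, these cells are described by their sums. Col1a1, a chain of type I collagen, stood at 14809 CPM (exact Poisson interval 14075 to 15572) and 6455 CPM (6064 to 6864). Dcn, which encodes the proteoglycan decorin, stood at 3622 CPM (3264 to 4009) and 10143 CPM (9652 to 10654). Pericyte and smooth muscle genes were also seen in this class. At 2 weeks Pdgfrb was found in 12 of 14 cells, Mylk in 10 and Tagln in 7, and at 4 weeks in 9, 3 and 4 of 16. Rgs5 had 171 UMIs in 3 of 14 cells, Notch3 had 21 in 3, Abcc9 had 22 in 2 and Myh11 had 10 in 2 of the 2-week cells. At 4 weeks Rgs5 and Myh11 had 0 UMIs in 16 cells, and Notch3 and Abcc9 had 5 each. Acta2, smooth muscle actin, was detected in 7 of 14 and 4 of 16 of these cells. After thinning each cell to 2000 UMIs, Acta2 was found in 1.29% of macrophage-like cells at 2 weeks (0.875 to 1.84) and 1.25% at 4 weeks. In neutrophil-like cells the shares were 4.90% (2.70 to 8.08, 14 of 286 cells) and 10.3% (4.24 to 20.1, 7 of 68 cells). Thinning left out 679 of 965 and 447 of 515 of these cells, and without it the shares were 5.91% and 7.96%. By contrast, 0 of 143 and 0 of 346 T cell-like cells had an Acta2 UMI after thinning, with exact upper bounds of 2.55% and 1.06%.

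In macrophage-like cells, genes induced by interferon-gamma and genes of glycolysis were lower at 4 weeks, and genes of lipid handling were higher. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), had 124 CPM at 2 weeks and 6.58 CPM at 4 weeks, a log2 ratio of -4.23 (-4.50 to -3.98). Saa3, an acute-phase serum amyloid, went from 365 to 21.9 CPM, a log2 ratio of -4.06 (-4.20 to -3.92). Arg1, the arginase that competes with Nos2 for arginine (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), went from 396 to 56.8 CPM, a log2 ratio of -2.80 (-2.90 to -2.71). Other genes with the lowest ratios were the uridine phosphorylase Upp1 (-3.06), the activin subunit Inhba (-2.57), Ifitm1 (-2.22), the hexokinase Hk2 (-2.14), the prostaglandin synthase Ptgs2 (-2.11), AA467197 (-1.95) and the arginine transporter Slc7a2 (-1.94).

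At the other end of the range, Retnla, a secreted protein of alternatively activated macrophages (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), had 26.6 CPM at 2 weeks and 152 CPM at 4 weeks, a log2 ratio of 2.52 (2.38 to 2.65). Only 1.33% and 6.82% of the cells of the class had a Retnla UMI. Cluster 20, outside the class, held 1646 and 10427 Retnla UMIs, against 530 and 2960 in the class. Vcam1, an adhesion molecule, had a log2 ratio of 2.34 (2.12 to 2.57), from 9.93 to 50.4 CPM. The lectin Mgl2 (1.73), the growth factor Igf1 (1.64), the signalling regulator Rgs1 (1.62) and the glycoprotein Gpnmb (1.56) followed. Ftl1-ps1 (2.36), Gm10076 (2.33) and Lyz1 (1.73) also ranked among the highest, but their values are uncertain. Of the 50-base windows in the 3' ends of their transcripts, 59.2%, 63.0% and 21.9%, respectively, also occur in transcripts of other genes. Mgl2 and Saa3 share 10.3% and 11.1% of theirs, Chil3 shares 17.1% and Gbp4 shares 19.8%.

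**Figure D2:**
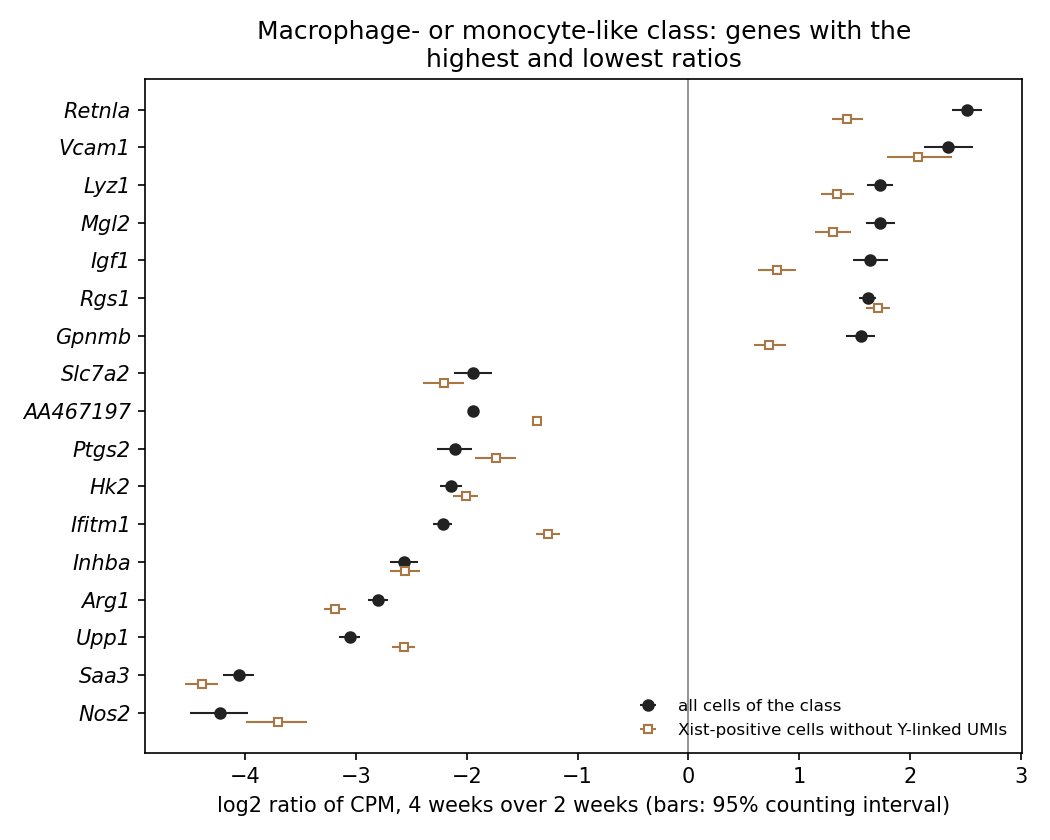
Log2 ratio of CPM, 4 weeks over 2 weeks, for genes among the 10 highest and 10 lowest of the macrophage-like class, leaving out those that share over 50% of their 3' windows with other genes. Filled circles are all cells of the class, open squares are cells with Xist and no Y-linked UMI, and bars are exact 95% counting intervals. Nos2 lies at -4.23 and Retnla at 2.52 over all cells, and at -3.71 and 1.43 in the Xist-positive cells.

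Of the interferon-gamma response list, 19 of 19 measured members had a lower CPM at 4 weeks. Their median log2 ratio was -0.87 (-0.92 to -0.81), at percentile 0 of 10000 random lists matched on expression. Cxcl9, a chemokine for activated T cells, went from 2682 to 1086 CPM (log2 ratio -1.30), the immunoproteasome subunit Psmb8 from 1208 to 745 CPM (-0.70), and the guanylate-binding protein Gbp4 from 283 to 88.0 CPM (-1.68). Of the MHC class II list, 4 of 10 members were higher and 6 lower. Its median was -0.05 (-0.11 to 0.08), at percentile 15.5. Cd74 (0.17), H2-Aa (0.42) and H2-Eb1 (0.30) were higher. H2-Ab1 had a ratio of -0.01, and of 0.31 in Xist-positive cells.

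Of the lipid handling macrophage list, 17 of 18 members were higher at 4 weeks, with a median of 0.66 (0.65 to 0.68) at percentile 100. Apoe, a lipid carrier, went from 5465 to 9391 CPM (0.78), Gpnmb from 32.5 to 95.6 CPM (1.56) and the fatty acid-binding protein Fabp4 from 4.96 to 15.2 CPM (1.61). Lgals3, at 3461 and 3503 CPM, had a log2 ratio of 0.02 that became -0.05 with TMM scaling. Of the list of alternatively activated or resident macrophage genes, 14 of 17 were higher, with a median of 0.65 (0.34 to 0.69) at percentile 100. Retnla and the platelet factor Pf4 were among the higher members, although the Pf4 ratio of 0.73 was -0.23 in Xist-positive cells. Cluster 4, outside the class, held 7163 and 3967 Pf4 UMIs, against 5258 and 8477 in the class, so its Pf4 went the other way. Arg1 and Chil3 (-1.17), which also belong to this list, went the other way.

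Different clusters held most of the macrophage-like class in each library: clusters 0 and 6, led by Cxcl9 and by Nos2, at 2 weeks, and clusters 1, 2 and 3, led by Cx3cr1, Clec4a1 and Chil3, at 4 weeks. Clusters 2 and 3 held similar shares of the class in both libraries, while cluster 9 held 1.05% and 12.5% and cluster 13 held 1.78% and 9.35%. Cells with Y-linked UMIs and no Xist UMI were found in the 2-week library alone, and 1 cell of the 4-week library had both. With Xist-positive cells alone, chosen after the data were seen, the median of the interferon-gamma list was -0.56, that of the lipid list 0.30, that of MHC class II 0.26, and that of the alternatively activated list -0.17, so the last changed direction. With excluded clusters put back, that list had a median of 0.25 (0.13 to 0.60).

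Further lists differed in several classes. All 14 members of the glycolysis and hypoxia list were lower at 4 weeks in macrophage-like cells (median -0.98, -0.999 to -0.93) and all 14 in dendritic cell-like cells (-0.65, -0.76 to -0.56), as were 12 of 13 in T cell-like cells (-0.86, -0.92 to -0.62). In neutrophil-like cells 11 of 14 were higher (0.13, 0.01 to 0.18). The type I interferon response list was higher in macrophage-like cells for 14 of 15 members (0.42, 0.35 to 0.46), in neutrophil-like cells for 13 of 14 (0.92, 0.59 to 1.20) and in dendritic cell-like cells for 11 of 15 (0.26, 0.08 to 0.36). In T cell-like cells 5 of 14 were higher (-0.24, -0.50 to -0.02). The list of genes induced by tissue dissociation was also higher at 4 weeks in every compared class. Its medians were 0.45, 0.46, 0.43 and 0.30 in macrophage-, neutrophil-, dendritic and T cell-like cells.

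**Figure D3:**
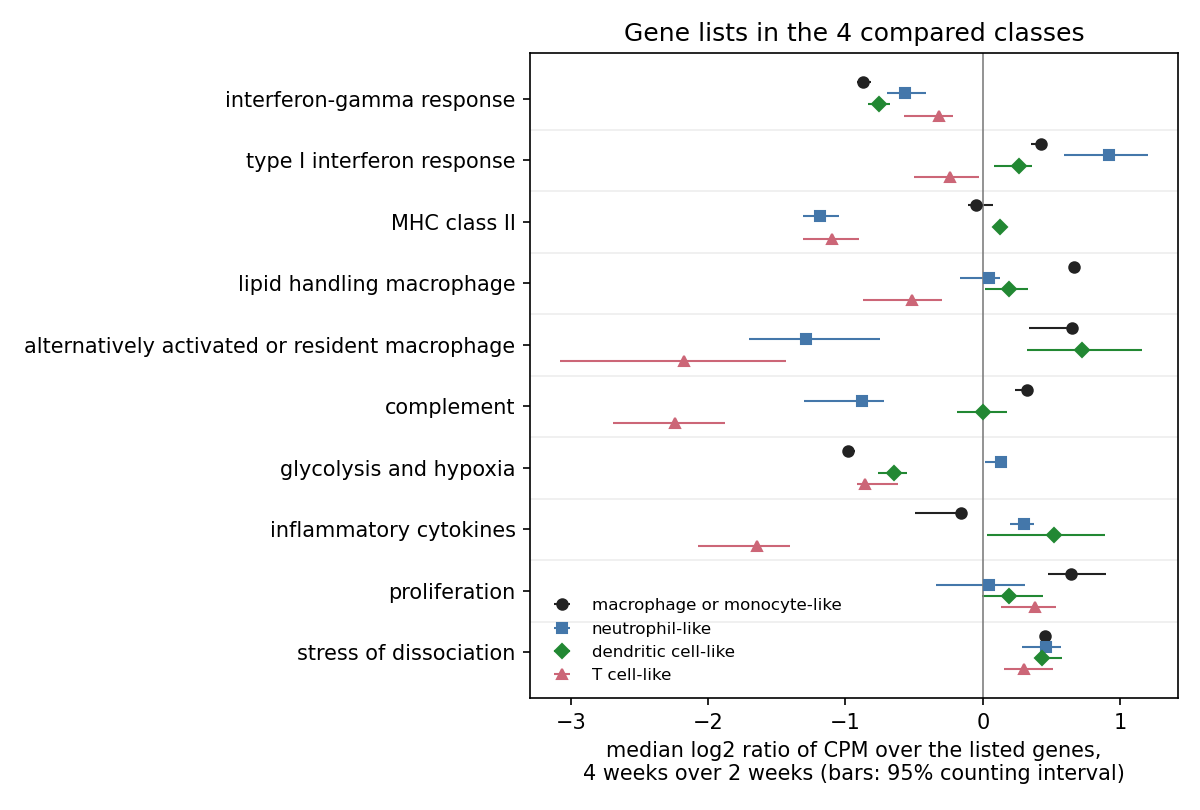
Median log2 ratio of CPM, 4 weeks over 2 weeks, for 10 gene lists in the 4 compared classes, marked by symbol and colour. Bars are 95% counting intervals from Poisson resampling. The interferon-gamma response list lies below 0 in each class, with medians of -0.87, -0.56, -0.75 and -0.32 in macrophage-, neutrophil-, dendritic and T cell-like cells. The macrophage gene C1qb was also lower in neutrophil- and T cell-like cells (-1.74 and -2.89). Whether their interferon-gamma medians come from RNA of macrophages was not tested.

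In neutrophil-like cells, genes of the type I interferon response were among the highest ratios at 4 weeks, while 17 of 18 members of the interferon-gamma response list were lower (-0.56, -0.70 to -0.42). The antiviral genes Rsad2 (302 and 929 CPM, log2 ratio 1.62, 1.47 to 1.77), Ifit1 (80.5 and 278 CPM, 1.79, 1.50 to 2.08), Ifit3 (1.52), Ifit3b (1.44) and Usp18 (1.57) were among the 10 highest ratios. So were the transcription factor Egr3 (2.16), Gm14005 (1.41), the granule protein Olfm4 (1.33), and again Ftl1-ps1 (2.5). Among the lowest were Cxcl9 (447 and 103 CPM, -2.11, -2.46 to -1.80), Gbp4 (-2.08), Nmt1 (-2.10), Ciita, the activator of MHC class II genes (-1.79), and Saa3 (-1.87). Gm42418, a transcript from a ribosomal RNA repeat region, went from 18728 to 4862 CPM (-1.95), and was lower in the other 3 compared classes too (-1.81, -1.43 and -1.88). The remaining lowest were C1qc (-2.0), C1qb (-1.74), Msr1 (-1.77) and Chil3 (-1.88), which are macrophage or monocyte genes. In the same class the complement list had a median of -0.88 (-1.30 to -0.72) and the MHC class II list -1.18 (-1.31 to -1.05). Ribosomal protein genes were lower for 89 of 95 members (-0.43, -0.46 to -0.39) and mitochondrial genes for 13 of 13 (-0.30, -0.38 to -0.25). Haemoglobin genes, which belong to red blood cells, were higher for 4 of 4 (8.99, 8.48 to 9.57). Over all kept cells, however, 5 cells of the 4-week library held 96.5% of its haemoglobin UMIs. The class of those cells was not examined, so this median may rest on very few cells.

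With other settings of filter or clustering, Chil3, Gbp4, Ciita, C1qb and Ifit3b each changed direction at least once in this class.

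In dendritic cell-like cells, chemokine genes were among those with the highest ratios. Ccl3 went from 9.97 to 50.3 CPM (log2 ratio 2.31, 1.72 to 3.01), Ccl4 from 20.7 to 71.5 CPM (1.78, 1.35 to 2.25) and Cxcl2 from 23.1 to 86.9 CPM (1.90, 1.50 to 2.35). Their UMIs lay in few cells, at most 13.1% of the class in either library without thinning. The unthinned share of cells with a Cxcl2 UMI was lower at 4 weeks, at 7.6% against 13.1%, although its CPM was higher. The shares for Ccl3 and Ccl4 were slightly higher at 4 weeks. Of the inflammatory cytokine list, which holds these genes, 8 of 13 measured members were higher and 5 lower. The mannose receptor Mrc1 (1.44), Gm26532 (1.63), Wdr89 (1.56), Gm47283 (1.48), Gm10076 (2.45) and Ftl1-ps1 (2.02) were also among the 10 highest. Wdr89 and Gm47283 share 12.3% and 34.4% of their 3' windows with other genes, and Gm47283 is annotated on chromosome Y. Lower at 4 weeks were the protease inhibitor Slpi (80.5 and 11.8 CPM, -2.76, -3.33 to -2.26), Upp1 (-2.48), and the interferon-inducible GTPases Gm4951 (-2.27) and Iigp1 (-1.57). Ifitm1 went from 2276 to 770 CPM (-1.56, -1.63 to -1.49). AY036118 (-2.04), Cnn3 (-1.64), Pla2g16 (-1.56), Cd200 (-1.53) and Bcl2l14 (-1.45) made up the rest. AY036118 overlaps Gm42418 on the opposite strand of chromosome 17 and shares 100% of its windows with another transcript, and Cnn3 shares 18.6% of its windows. The interferon-gamma list was lower for 18 of 18 members, with a median of -0.75 (-0.84 to -0.67), and the MHC class II list was higher for 7 of 10 (0.12, 0.07 to 0.16).

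T cell-like cells had lower levels of effector genes and higher levels of genes of naive and memory T cells at 4 weeks. Of the cytotoxic list, 10 of 14 members were lower, with a median of -0.29 (-0.42 to -0.08) at percentile 0.16. The chemokine Ccl5 went from 4385 to 3420 CPM (-0.36, -0.42 to -0.30) and the granule gene Nkg7 from 2598 to 1731 CPM (-0.59, -0.67 to -0.50). The lowest ratios in the list were those of Gzmb (-2.42, -2.73 to -2.13), Ifng (-2.04, -2.22 to -1.86) and Prf1 (-1.91, -2.16 to -1.67). The share of cells with an Ifng UMI was nonetheless similar, at 30.1% and 29.1%. The members with the largest absolute ratios were higher, but in few cells. Gzmc had 3 and 58 UMIs (log2 ratio 3.14, 1.73 to 5.67), in 0.54% and 2.43% of the cells. Gzmf had 0 and 120 UMIs, at least 21.1-fold higher against a floor of 3 counts over the library, and with an exact interval that reaches down to a log2 ratio of 4.08, but all 120 came from 1 cell, and Gzmf shares 12.8% of its 3' windows with other granzymes. With Gzmf at that bound the list median was unchanged at -0.29. Of the checkpoint list, 7 of 11 members were lower, with a median of -0.31 (-0.62 to 0.03) at percentile 1.05. Havcr2 (-1.54, -2.03 to -1.06), Lag3 (-1.18, -1.49 to -0.87) and the costimulatory receptor Tnfrsf9 (-1.14, -1.43 to -0.85) were lower, while the transcription factor Tox was higher (1.36, 0.85 to 1.95) and Cd244 had 3 and 17 UMIs (1.40, -0.21 to 3.99).

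Of the naive or memory T list, 9 of 10 members were higher, with a median of 0.40 (0.21 to 0.55) at percentile 99.9. The transcription factor Tcf7 went from 58.3 to 154 CPM (1.38, 0.93 to 1.89). S1pr1 (0.59, 0.13 to 1.10), the survival gene Bcl2 (0.52, 0.22 to 0.83) and the cytokine receptor Il7r (0.30, 0.10 to 0.50) were higher as well, though Il7r was at -0.013 with the mean over cells of scaled counts. The CD8-led cluster 11 held 73.7% of these cells at 2 weeks and 59.7% at 4 weeks, and the Tnfrsf4- and Cd4-expressing cluster 18 held the rest. Macrophage transcripts were lower in this class at 4 weeks too: C1qb went from 300.5 to 40.3 CPM, and 6 of 6 complement genes were lower (median -2.24). With each library clustered alone, the naive or memory median was 0.25 (0.07 to 0.40). With the mean over cells of scaled counts it was 0.28, the checkpoint median was -0.05 and the cytotoxic median -0.15, and in Xist-positive cells the cytotoxic median was -0.58.

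The share of cycling cells, those with an Mki67 or Top2a UMI after thinning to 2000 UMIs, was 2.59% at 2 weeks (2.11 to 3.16, 96 of 3703 cells) and 4.28% at 4 weeks (3.70 to 4.93, 184 of 4296). The difference was 1.69 points (0.892 to 2.49), and 1091 and 981 shallower cells were left out. Without thinning the shares were 7.13% and 7.77%, a difference of 0.636 points whose interval included 0 (-0.395 to 1.66). The cycling cluster 21 held 17 of the 96 and 71 of the 184 cells. In T cell-like cells the thinned shares were 7.69% (3.90 to 13.3) and 9.25% (6.41 to 12.8), and in macrophage-like cells 1.47% (1.02 to 2.04) and 1.92% (1.43 to 2.5). For neutrophils, which do not divide, they were 1 of 286 and 1 of 68 cells.

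Kit itself (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722) was seen in few cells of this lineage-traced population. After thinning, 1.30% of cells at 2 weeks (0.957 to 1.72) and 1.14% at 4 weeks (0.845 to 1.51) had a Kit UMI, and without thinning 3.78% and 2.90%. Dendritic cell-like cells had the highest thinned share of the compared classes, at 6.48% (3.88 to 10.0) and 6.40% (4.23 to 9.24), against 0 of 143 and 2 of 346 T cell-like cells. Median depths were 8205 and 7042 UMIs in dendritic cell-like cells and 3770 and 3022 in T cell-like cells before thinning. In macrophage-like cells the shares were 0.820% and 0.368%, a difference of -0.451 points (-0.938 to -0.025). Both lie below the exact upper bounds of the T cell-like shares, 2.55% and 2.07%. With so few T cell-like cells, that background cannot tell whether macrophage-like cells stand above it. No change is therefore read from the log2 ratio of Kit in macrophage-like cells, -1.12. In dendritic cell-like cells the ratio was -0.55, while the thinned shares differed by -0.071 points (-4.12 to 3.59). Of the neutrophil-like cells 6 of 965 and 0 of 515 had a Kit UMI unthinned. Transcripts of the tdTomato reporter were found, after thinning, in 6.16% of cells (5.4 to 6.98) at 2 weeks and 2.14% (1.73 to 2.62) at 4 weeks, and without thinning in 16.6% and 7.01%. No class in a tdTomato-positive sort should lack the reporter, so no background share can be given for it.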

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

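The tests of free RNA and of cell pairs in this part were chosen after the values they rest on had been seen, while the reporter test and the tests of the interferon-gamma list were set before theirs. In the 2-week library, 919 of 4794 cells had UMIs of Y-linked genes (Ddx3y, Uty, Eif2s3y or Kdm5d) and none of Xist, while 2050 had Xist alone. The report's comparisons do not describe these genes; a fixed list of sex- and strain-linked genes that holds them had a median log2 ratio of -6.91 in macrophage-like cells. In the 4-week library 0 of 5277 cells had Y-linked UMIs without Xist, which allows an exact upper bound of 0.070%. At 2 weeks the Y-only cells made up 38.7% of typed macrophage-like cells (36.4 to 41.0), 45.3% of dendritic cell-like cells (38.6 to 52.1) and 13.2% of neutrophil-like cells (9.37 to 17.9).

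The tables argue against free RNA: among cells with at least 4000 UMIs, those with both kinds of UMI numbered 129, which is 0.251 of the number expected if the kinds fell into cells independently. Cells of the graft donor lack the reporter and should be removed by the tdTomato sort, and a tdTomato UMI was found after thinning in 4.70% of Y-only cells (3.39 to 6.32) and 6.37% of Xist-only cells (5.29 to 7.59). The Y-only share lies above the bound set beforehand against such cells, 0.5 times the upper limit of the Xist-only share, but its interval reaches below that bound, so donor cells stay open. Another open possibility is that the 2-week library holds cells of more than 1 animal. The labels used here give no sex, and no biological explanation was tested.

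In cluster 17, which carried T cell and macrophage markers, 58 of the 187 cells of the 2-week library had both Xist and Y-linked UMIs. That is 31.0% (24.5 to 38.2), against 2.03% (1.53 to 2.64) of macrophage- and T cell-like cells, and 27.9% of 10000 random pairs of a T cell-like and a macrophage-like cell. The median depth was 11230 UMIs in the cluster and 11539 in the pairs. The share of cells with a Cd3e UMI was 139.6 times that of macrophage-like cells. This cannot decide on free RNA, because the cluster was set apart by T cell markers that include Cd3e. The values may come from droplets with 2 cells. No biological explanation, such as cells in contact in the tissue, was tested.

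The interferon-gamma response list was lower at 4 weeks in macrophage-like cells, with a median of -0.87. With Xist-positive cells alone it was -0.555, so the Y-bearing cells of the 2-week library do not account for the whole difference. That setting also leaves out cells with neither kind of UMI, so how much of the smaller median comes from Y-bearing cells was not tested. TMM scaling gave -0.945, which argues against the total count as the cause. Within the 2-week library, however, the list stood 0.496 higher (0.46 to 0.57) in Y-only than in Xist-only macrophage-like cells. Cells that differ in Y-linked UMIs thus differed in this list at 1 time point, so variation between animals may account for part of the difference. Time itself stays an open explanation, untested without replicates.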

How the results depend on the processing

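The highest doublet scores removed, Xist-positive cells alone and excluded clusters put back were alternatives chosen after the data were seen. No paired analysis was possible because each time point has 1 library. Over 13 main results, 112 of 147 alternative values stayed within the counting interval, 33 moved beyond it in the same direction or from near 0, and 2 turned. For 85 named genes, 1090 of 1105 values kept their direction and 15, in 9 genes, turned. Scrublet called no doublets, so keeping them changed nothing and gave no value, and clustering settings leave the cycling share of all cells unchanged. Neutrophil-like cells are limited by their depth and rare classes by their number of cells. Where a cause is not stated, the cause was not tested.

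A minimum of 800 genes gave a macrophage-like share difference of 2.27 points, a lipid handling median of 0.69 and a neutrophil Ifit3b ratio of -0.58. A mitochondrial limit of 20% gave 8.73 points, 0.69 for the lipid list and 0.25 for neutrophil Chil3. Resolution 0.5 gave a neutrophil-like difference of -14.2 points, 0.72 for the lipid list and 0.70 for the alternatively activated list. Resolution 2.0 gave -6.16 points, 0.71 for the lipid list and 0.015 for neutrophil C1qb. With 4000 variable genes the neutrophil-like difference was -13.7 points, the interferon-gamma median -0.92 and the lipid median 0.77. Clustering each library alone gave -7.32 points, 0.75 for the lipid list, and 1.05, 0.56 and 0.34 for neutrophil Gbp4, Chil3 and Ciita. Leaving out proliferation and stress genes gave 0.69 for the lipid list.

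TMM scaling, which shifted macrophage-like ratios by -0.07, gave -0.95 for the interferon-gamma list, -0.12 for MHC class II, 0.59 for the lipid list and -0.054 for Lgals3. The mean over cells gave 0.72 for the lipid list and -0.013 for Il7r in T cell-like cells. The cycling difference was 0.879 points with cells thinned to 1000 UMIs and 0.636 without thinning.

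Removing the highest doublet scores gave a macrophage-like difference of -2.48 points, since 1 cluster then failed a naming rule, with 0.60 for the lipid list, 0.072 for H2-Ab1, -0.14 for Lgals3 and 0.49 for neutrophil Chil3. Xist-positive cells alone gave share differences of 8.99 (macrophage-like), -8.38 (neutrophil-like), 3.22 (dendritic cell-like) and 2.67 points (T cell-like). Their list medians were -0.56 for interferon-gamma, 0.26 for MHC class II, 0.30 for lipid handling, -0.17 for alternatively activated and -0.58 for cytotoxic genes in T cell-like cells, with ratios of 0.31 for H2-Ab1 and -0.23 for Pf4. Putting excluded clusters back gave -14.8 points for the neutrophil-like difference, 0.52 for the lipid list, 0.25 for the alternatively activated list, 0.021 for H2-Ab1 and -0.013 for Lgals3.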

Other observations

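The difference between Y-only and Xist-only macrophage-like cells of the 2-week library went well beyond sex-linked genes. Over 680 and 1077 cells, the list of alternatively activated or resident macrophage genes had a median log2 ratio, Y-only over Xist-only, of -2.07 (-2.25 to -1.72), and the lipid handling list of -0.97 (-1.01 to -0.83). Retnla had 9 UMIs in Y-only and 516 in Xist-only cells. Pf4 stood at 89.1 and 498 CPM, Folr2 at 11.6 and 57.3 CPM, Spp1 at 101 and 387 CPM and Apoe at 3434 and 7646 CPM. The type I interferon list (0.56, 0.49 to 0.67) and the MHC class II list (0.56, 0.51 to 0.59) were higher in Y-only cells, as were Cxcl9, at 3378 and 1928 CPM, and Nos2, at 148 and 89.4 CPM. C1qa differed little, at 2370 and 2268 CPM. This comparison was made after the data were seen, and the cells differ in cluster membership as well.

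Further lists in macrophage-like cells pointed in several directions at 4 weeks. Complement genes were higher for 7 of 11 members (median 0.32, 0.23 to 0.35) and proliferation genes for 15 of 17 (0.64, 0.47 to 0.89). The progenitor list had 5 of 7 members lower (-0.94, -0.99 to -0.53), cholesterol synthesis 8 of 11 (-0.28, -0.38 to -0.06), inflammatory cytokines 10 of 16 (-0.16, -0.50 to -0.13) and MHC class I 9 of 13 (-0.12, -0.26 to -0.04). Matrix genes were higher for 11 of 16 (0.34, 0.05 to 0.56), whereas matrix remodelling genes were split 6 to 6 (-0.16, -0.50 to -0.09). The TGF-beta target (0.04), osteochondrogenic (0.08), smooth muscle modulation (0.04), vascular growth signal (0.01), tissue residence (0.11), oxidative phosphorylation (-0.05), contractile (0.28), checkpoint (-0.12) and naive or memory T (0.02) lists had medians at percentiles from 5.90 to 68.5. The cytotoxic list was lower for 7 of 7 measured members (-0.98, -1.20 to -0.64). Inflammatory cytokines had a median of 0.52 (0.03 to 0.89) in dendritic cell-like cells, 0.30 (0.20 to 0.37) in neutrophil-like cells and -1.64 (-2.07 to -1.40) in T cell-like cells.

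Some genes had similar ratios in each compared class. Gm10076 had log2 ratios of 2.33, 2.25, 2.45 and 2.01 in macrophage-, neutrophil-, dendritic and T cell-like cells. Gm42418 had -1.81, -1.95, -1.43 and -1.88, and AY036118 had -1.66, -1.59, -2.04 and -1.86. Whether read length or library batch differed between the libraries is not given in the sources used here, so these ratios cannot be read as expression alone. Ribosomal protein genes took 12.9% of UMIs at 2 weeks and 15.2% at 4 weeks, and mitochondrial genes 2.88% and 3.49%. The list medians were 0.13 for ribosomal protein and 0.17 for mitochondrial genes in macrophage-like cells, and 0.22 and 0.33 in dendritic cell-like cells, in contrast to the negative medians of neutrophil-like cells.

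Haemoglobin UMIs were found in 5.05% of cells at 2 weeks (4.44 to 5.71) and 8.43% at 4 weeks (7.70 to 9.22). In each library 5 cells with at least 100 haemoglobin UMIs held most of them, 97.6% and 96.5%. The haemoglobin list had a median of 0.02 in macrophage-like and 8.99 in neutrophil-like cells. The class of those 5 cells was not examined, so the neutrophil-like value may rest on very few cells.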
